A study of Mus musculus with 10 samples.

How the data were processed

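Messenger RNA levels were measured by RNA sequencing in 10 libraries of mouse cells that had been sorted by flow cytometry, 3 of splenic CD45-negative cells, 3 of splenic CD45-positive cells and 4 of tumor CD45-positive cells. The labels call the sorted population EPC without spelling the abbreviation out, and the abbreviation is used here as given. Per the labels' protocols, a sequencing company extracted total RNA with TRIZOL and made the libraries by the kit manufacturer's instructions. Neither the kit, nor the selection of messenger RNA, nor the use of strand is named there. The genome build was GRCm38.p6 per the submitters' processing notes. The aligner, the program that estimated expression, their versions and the annotation release are not given in the sources used here.

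The authors deposited 1 table per library with 1 value for each of 61685 RefSeq messenger RNA models, 1843 of which were numbered copies of another model. No header or label names the unit. The deposited values were read as FPKM (fragments divided by transcript length in kilobases and by the number of mapped fragments, as usually scaled) for these reasons. They had 2 decimals, their sums differed between libraries from 801072 to 1367791, and multiplied by transcript length in kilobases they summed to between 953307 and 1137767 in every library, near the value that FPKM requires. Transcript lengths came from GENCODE transcripts matched to the models by RefSeq accession and were known for 23223 of the models. The length-weighted sums cover these models alone. What share of reads was mapped, and what filters the authors applied before they deposited the FPKM values, is not given in the sources used here.

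The values of all models of a gene were summed, which gave 17603 genes from the 60167 models that carried a gene symbol. The 1518 models without one held 0.423% to 1.06% of the summed FPKM of a library and entered no test. Mitochondrially encoded transcripts, the immunoglobulin constant genes Ighm, Ighd and Igkc, the T cell receptor constant genes Trac, Trbc1 and Trbc2, and Ahsp, Mx1 and Mx2 had no value in these tables and were not analysed here. Counts of reads cannot be restored for every gene from FPKM, but the lowest values of single-model genes of 400 to 1200 bases rose in steps that 1 fragment is worth. That step lay between 0.0496 and 0.0565 FPKM for a transcript of 1 kilobase, which puts the depth at about 17700000 to 20200000 fragments per library. At that depth a gene of 1 kilobase at 1 FPKM rests on about 17.7 to 20.2 fragments, so values below 1 FPKM are coarse. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

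Each comparison was tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity-dependent prior variance and no covariate, over genes at 1 FPKM or more in at least 3 of the libraries compared. Splenic CD45-positive libraries were set against splenic CD45-negative libraries (same organ, opposite CD45 gate) and tumor CD45-positive libraries against splenic CD45-positive libraries (same gate, other tissue). Only the libraries of the groups compared entered a fit. A gene below 1 FPKM in every library of 1 group passed the filter through the other group alone, so it could be called in 1 direction only. Tumor CD45-positive and splenic CD45-negative libraries differ in tissue and gate together and were not tested against each other. A gene was called higher or lower at a Benjamini-Hochberg adjusted p below 0.05, and all adjusted p-values of genes are from limma. Nothing in the labels says that replicates came from separate mice, so the p-values measure only the spread between these samples, which may be technical. The replicate numbers that the groups share showed no consistent pairing of the libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

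Before the data were examined, 28 gene lists, the groups, the tests, the threshold, most of the other settings and a rule for the genes to be named were written down. The design at that stage assumed counts and gave limma on log2 values as the test for the case of normalized values, which applied here. The lists covered erythroid maturation, haem synthesis and iron uptake, erythroid transcription factors, haematopoietic stem and early progenitor genes, cell cycle, cytosolic ribosomal proteins, nuclear genes of oxidative phosphorylation, glycolysis and hypoxia, the unfolded protein and amino acid stress response, type I interferon, interferon-γ, MHC class I and class II presentation, immune checkpoints, immunosuppressive enzymes and cytokines, inflammatory cytokines and chemokines, immediate early and dissociation genes, mitochondrially encoded transcripts, and markers of granulocytes, monocytes and macrophages, dendritic cells, T and NK cells, B cells, megakaryocytes and platelets, mast cells and basophils, endothelium, epithelium and carcinoma, and fibroblasts and stroma. Of these lists 27 had values. Lists with at least 3 tested genes were compared with all other genes by limma's camera test with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The numbers of members called were also taken with p-values adjusted over the list alone.

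The rule for named genes took Ptprc, Tfrc, Kit, Klf1, Hbb-bs, Hba-a1, Cd274 and Arg1 in every case. It added the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap between the groups and whose mean was at least 10 FPKM in the higher group, leaving out predicted genes and pseudogenes. From each list it took up to 2 rising and 2 falling members with the smallest adjusted p, or the 2 members with the highest mean where none passed. Some of the genes it named are not reported here. Genes outside the rule (the histone group as a whole, Alas2, Bpgm, the globin copies and the transcripts of highest mean per group) were chosen after their values were seen. Globins were counted as 10 genes of the Hba and Hbb clusters. Hbb-b1, Hbb-b2 and Hba-a1 held nearly all of the globin signal while Hbb-bs was near 0, and reads of such near-identical copies may have been divided among them in either way, so values of single globin genes and of single histone genes are uncertain.

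The other settings fixed at that stage were a pseudocount of 0.1, no filter, a filter of 5 FPKM, removal of the globin genes from the totals and the fit, 1 fit over all 10 libraries, the replicate number as a block, a minimum log2 change of 1, leaving out each library in turn, and camera with an estimated correlation or fry for the lists. Scaling to a common sum, trimmed-mean scaling, median-ratio scaling and the averaging of tumor libraries that were close to each other were added after the data had been seen. With fewer libraries the filter removes genes found in 1 group alone, so the fits without a library, and that with tumor replicates 2 to 4 averaged, were also made over the same genes as with all libraries, a setting added after the data had been seen. The fitting step was tested on simulated data in which 200 genes were changed by a known amount. Of genes changed by 1 on the log2 scale 30% were recovered in the setting of the CD45 comparison (9728 genes) and 33% in that of the tumor comparison (11463 genes), and of genes changed by 2 on the log2 scale 78% and 87%. False calls were 6 of 114 and 12 of 132, and the share in the tumor setting was above the adjusted p threshold. The changed genes were drawn from those with higher values. They were far fewer than the genes called in the real data, so recovery there may differ. Similarity of replicates was checked by Pearson correlation, by principal components and by a chi-square of the fragments implied by the depth step. Tumor replicates 2 and 3 came closest to counting noise, with a median ratio of 1.16 to the value that counting alone gives. The counts still differed by more than counting noise (chi-square p = 6.02e-47), so they were not counted as 1 library. Repeat libraries of 1 sample would differ in that way too, so this does not show that the 4 tumor libraries come from separate animals.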

Results

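Gene expression was measured in sorted cells, labelled EPC, from tumor-bearing C3H/HeN females. The tumors had been grown from SCC7 cells, a mouse squamous cell carcinoma line that the labels use as a model of head and neck cancer. CD45, the surface phosphatase of white blood cells, divided the sorted cells into 3 groups: splenic CD45-negative (n = 3), splenic CD45-positive (n = 3) and tumor CD45-positive (n = 4). The deposited FPKM values implied a depth of 17700000 to 20200000 fragments per library. Between 7853 and 7960 genes reached 1 FPKM in splenic CD45-negative libraries, 9828 to 10890 in splenic CD45-positive and 10728 to 10945 in tumor CD45-positive libraries.

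Haemoglobin transcripts took 62.9% ± 0.561 (SD, n = 3) of the summed FPKM in splenic CD45-negative libraries, 41.3% ± 11.4 (SD, n = 3) in splenic CD45-positive and 3.99% ± 4.30 (SD, n = 4) in tumor CD45-positive libraries. The first principal component of log2 values held 78.3% of the variance and separated splenic CD45-negative from tumor libraries, with splenic CD45-positive libraries between them. The second held 16.1% and set splenic CD45-positive libraries apart. Pearson correlations across genes, which are not independent replicates, were 0.993 to 0.994 among splenic CD45-negative libraries, 0.998 to 0.999 among tumor replicates 2 to 4 and 0.982 to 0.984 between these and tumor replicate 1. Splenic CD45-positive libraries were farthest apart (0.887 to 0.977), and replicate 2 stood apart from the other two. Its Ptprc value was 39.2 FPKM against 265 and 153, and its Cd79a value was 64.9 FPKM against 593 and 469. Tumor replicate 1 stood apart from the other tumor libraries, with 10.4% of its FPKM in globins against 1.80% to 1.87%.

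**Figure D1:**
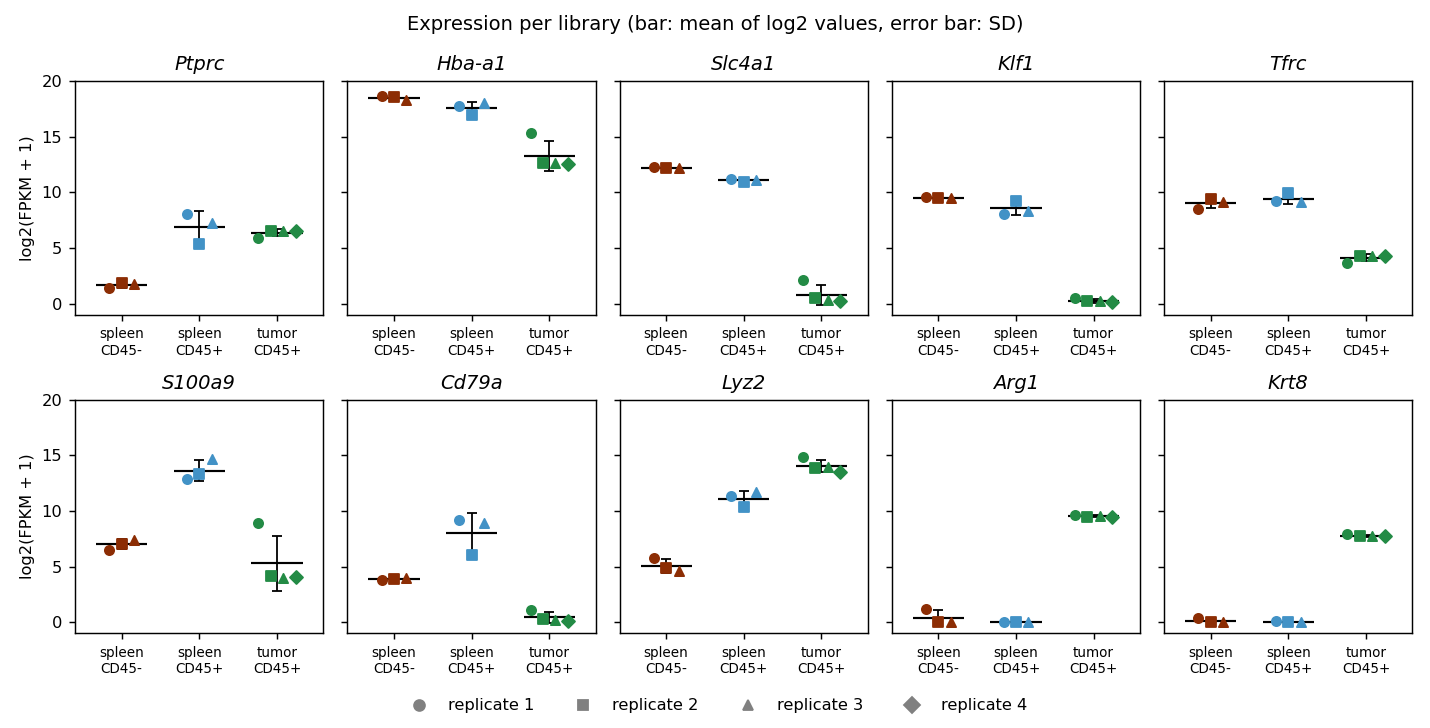
Expression per library of Ptprc (CD45), erythroid genes (Hba-a1, Slc4a1, Klf1, Tfrc), the granulocyte gene S100a9, the B cell gene Cd79a, the macrophage gene Lyz2, Arg1 and Krt8, as log2(FPKM + 1), for 3 splenic CD45-negative, 3 splenic CD45-positive and 4 tumor CD45-positive libraries. Each point is a library, the horizontal bar is the mean of the log2 values and the error bar their SD; Klf1 is near 0 in the tumor libraries, and Arg1 and Krt8 are near 0 in both splenic groups.

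The first comparison set CD45-positive against CD45-negative cells of the spleen and asked how the cells on either side of the gate differed. Splenic CD45-positive cells held transcripts of granulocytes, macrophages, B cells and T cells that were low in CD45-negative cells, and lower levels of genes of late red cell formation. Ptprc, which encodes CD45 (Entrez gene 19264, chromosome 1 of GRCm38.p6, 138062859 to 138175756), rose from 2.17 ± 0.485 to 153 ± 113 FPKM (SD, n = 3 each), a log2 change of 5.23 ± 0.63 (SE) with an adjusted p of 1.16e-03 by limma, and of 4.64 without CD45-positive replicate 1 and 6.01 without replicate 2. S100a9, a calcium-binding protein abundant in neutrophils (chromosome 3, 90692630 to 90695721), rose from 130 ± 39.0 to 14349 ± 9853 FPKM. Klf1, an erythroid transcription factor (chromosome 8, 84901982 to 84905291), fell from 737 ± 44.9 to 404 ± 183 FPKM.

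Erythroid genes fell as a group. Of 31 tested genes of erythroid maturation 18 fell and none rose. Of 20 genes of haem synthesis and iron uptake 13 fell and none rose, and of 19 erythroid transcription factors 7 fell and 3 rose. Adjusted over the list alone, 18, 14 and 7 fell. The median log2 changes were -0.78, -0.81 and -0.53 in the deposited values, while the median of all 9728 tested genes was 0.673. With trimmed-mean scaling, which moved the median of all genes to -0.175, they were -1.68, -1.75 and -1.45. Camera placed all of them below other genes (adjusted p = 2.15e-21, 6.11e-14 and 8.85e-07). With an estimated correlation the adjusted p was 0.0105 for maturation, 0.479 for haem synthesis and 0.707 for transcription factors. The smallest adjusted p-values in these lists belonged to Dmtn, a protein of the red cell membrane skeleton, and Tspo2 (log2 -1.19 each), Urod and Slc25a38 (haem synthesis, log2 -1.08 and -1.01), and E2f2 and Epor, the erythropoietin receptor (log2 -1.14 and -1.28). Among the transcription factors that rose were the signal transducers Stat5a and Stat5b (log2 1.27 for both), and Stat5b was at 0.41 with an adjusted p of 0.130 after trimmed-mean scaling and 0.0994 after median-ratio scaling. Hba-a1 (chromosome 11, 32283672 to 32284486) fell from 366596 ± 47313 to 202506 ± 73773 FPKM (log2 -0.92, adjusted p = 0.0439). Hbb-bs, listed at 2.87 and 0.867 FPKM, fell by 1.07 on the log2 scale. Tfrc, the transferrin receptor, was at 539 ± 151 and 707 ± 223 FPKM. Its log2 change of 0.39 did not pass (adjusted p = 0.312) and turned to -0.55 with trimmed-mean and median-ratio scaling. Klf1 missed the threshold without any of the splenic CD45-negative libraries (adjusted p = 0.0720 to 0.103) or without CD45-positive replicate 1 or 3 (0.106 and 0.0956), with no filter (0.0618) or after scaling to a common sum (0.205). The call of Hba-a1 was lost without any of the CD45-negative libraries (0.0740 to 0.177) or without CD45-positive replicate 2 (0.209). It was also lost with no filter (0.899), in 1 fit over all libraries (0.240), with the replicate number as a block (0.212) and after scaling to a common sum (0.117). Hbb-bs missed it without CD45-negative replicate 1 or 2 (0.105 and 0.0836) or CD45-positive replicate 1 (0.0659), or with no filter (0.0600). The calls of Urod and Slc25a38 were lost after scaling to a common sum (0.0558 and 0.101).

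Markers of granulocytes, monocytes and macrophages, B cells, and T and NK cells rose as groups. All 22 granulocyte markers rose (median log2 4.54, camera adjusted p = 9.61e-10, and 0.809 with an estimated correlation). The largest rises were those of Ltf, Lcn2, Ngp, S100a9, Retnlg and Camp, all of them abundant in neutrophils, with log2 changes of 6.86, 6.82, 6.63, 6.60, 6.34 and 6.30 (5.69 for both Camp and Retnlg without CD45-positive replicate 3). Monocyte and macrophage markers rose for 15 of 19 genes (median log2 3.48, adjusted p = 7.29e-03, and 0.809 with an estimated correlation). Among them were Itgam (log2 5.30) and the lysozyme gene Lyz2, which rose from 34.3 ± 15.6 to 2364 ± 1021 FPKM. All 14 B cell markers rose (median log2 3.93, adjusted p = 0.0133, and 0.809 with an estimated correlation), Ms4a1 by 4.41 and Bank1 by 3.91 on the log2 scale (5.46 and 4.80 without CD45-positive replicate 2). T and NK cell markers rose for 16 of 17 genes (median log2 2.68, adjusted p = 9.16e-03, and 0.809 with an estimated correlation), Cd3d by 3.68 and Gzma by 3.98 on the log2 scale (Gzma by 4.85 without CD45-positive replicate 2). Genes of MHC class II presentation rose for 12 of 13 genes (median log2 4.03, adjusted p = 0.0480, and 0.809 with an estimated correlation), H2-Ob among them (log2 4.23, and 5.26 without CD45-positive replicate 2). Without CD45-positive replicate 3, over the same genes, the macrophage, B cell, T and NK cell and class II lists lost their calls (adjusted p = 0.0568, 0.0964, 0.0964 and 0.318), and without replicate 1 the class II list did (0.0755). With the filter applied again to the libraries left, which removes genes, the T and NK list lost its call without replicate 1 or 3 (0.0826 and 0.226) and the class II list without replicate 3 (0.129). Adjusted over the list alone, 22, 19, 14, 17 and 12 genes of these lists rose. Itgam, Bank1 and Cd3d were below 1 FPKM in every CD45-negative library, so the filter left them no call but a rise. How many other members entered in this way was not counted. Beside these groups stands the low level of B, T and macrophage transcripts in CD45-positive replicate 2, whose B cell markers had a median ratio of 0.113 to replicate 1, T and NK cell markers 0.132, macrophage markers 0.051 and granulocyte markers 1.14. Against replicate 3 these ratios were 0.133, 0.181, 0.211 and 0.38.

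Glycolysis and hypoxia genes rose for 24 of 26 genes (25 adjusted over the list alone), with a median log2 change of 2.34, Pkm by 4.88 and Pgam1 by 3.79. The camera adjusted p was 5.09e-05, and 0.707 with an estimated correlation. Of 13 immunosuppressive enzymes and cytokines 11 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 7.90e-03, and 0.809 with an estimated correlation). Among the rising members were Cybb and Ncf1, subunits of the phagocyte oxidase (log2 5.58 and 5.34). The falling member was Artn, a neurotrophic factor, from 8.19 ± 0.861 to 3.72 ± 0.501 FPKM, a call lost after scaling to a common sum (adjusted p = 0.0924). Arg1, arginase of suppressive myeloid cells, was not tested, since it stayed at 1.26, 0.03 and 0 FPKM in the CD45-negative and at 0, 0 and 0.03 FPKM in the CD45-positive libraries. Cd274, which encodes PD-L1, was below the filter, at 0.643 ± 0.218 and 7.70 ± 7.64 FPKM. Early progenitor genes rose for 9 of 11 genes (11 adjusted over the list alone; camera adjusted p = 0.0106, and 0.809 with an estimated correlation), including Spi1, a myeloid and lymphoid regulator (log2 4.52), and Kit, the stem cell factor receptor, from 0.340 ± 0.044 to 2.11 ± 0.592 FPKM. Kit was below 1 FPKM in every CD45-negative library, so it could only be called higher.

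The cell cycle list lay below other genes (camera adjusted p = 2.29e-11, and 0.809 with an estimated correlation), with a median log2 change of -0.60, but of its 32 genes Ube2c alone passed as lower (log2 -0.79, adjusted p = 0.0240), and none adjusted over the list alone. The CD45-positive libraries did not go the same way. The median of the list was 140, 147 and 156 FPKM in CD45-negative replicates 1 to 3. It was 70.1 and 79.6 FPKM in CD45-positive replicates 1 and 3, but 214 FPKM in replicate 2. The Ube2c call was lost without CD45-negative replicate 1 or 2 (adjusted p = 0.0770 and 0.0930) and without CD45-positive replicate 1 or 3 (0.0926 and 0.0554), and after scaling to a common sum (0.279). The type I interferon list had members on both sides, 5 of 25 higher and 7 lower, also when adjusted over the list alone. Zbp1 and Ifit2 were higher (log2 3.08 and 1.25, and 4.0 for Zbp1 without CD45-positive replicate 2), Usp18 and Oasl1 lower (log2 -1.14 and -1.20), and the call of Ifit2 was lost after trimmed-mean and median-ratio scaling (adjusted p = 0.104 and 0.0554). Its camera adjusted p was 4.66e-06 in the downward direction, 0.809 with an estimated correlation and 0.0615 without CD45-positive replicate 2 (0.0290 over the same genes). Nuclear genes of oxidative phosphorylation had a median log2 change of 0.02, which is below that of all genes (camera adjusted p = 6.54e-04 downward, and 0.809 with an estimated correlation). Their 2 called members, Cox5a and Ndufb5, were higher by 0.84 and 0.79 in the deposited values and lower by trimmed-mean and median-ratio scaling. Neither passed adjusted over the list alone. Cox5a also missed the threshold without CD45-negative replicate 2 or 3 (0.0635 and 0.0846) or CD45-positive replicate 1 (0.0619) or the globin genes (0.0570), and Ndufb5 without CD45-negative replicate 1 or 2 (0.0521 and 0.0737).

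Other lists did not pass camera in this comparison. Mast cell and basophil markers were higher for all 4 tested genes, with Mcpt8 at log2 4.49 (5.10 without CD45-positive replicate 2) and Prss34 at 4.35 (adjusted p = 0.0501). Of 23 immediate early and dissociation genes 18 were higher, Klf2 by 4.44 (0.141; 5.31 without CD45-positive replicate 2). Also higher were 9 of 13 inflammatory cytokines and chemokines (0.141), 11 of 14 checkpoint genes (0.200), 1 of which changed sign under another scaling, and 4 of 5 dendritic cell markers, with Ccr7 and Siglech among them (0.378). The same held for 6 of 15 MHC class I genes (0.820), 7 of 12 interferon-γ induced genes (0.841) and 2 of 5 endothelial markers, Pecam1 and Erg (0.853). Both tested stroma markers, Thy1 and Fn1, rose by 3.57 and 4.13 on the log2 scale (Thy1 by 4.36 without CD45-positive replicate 2) and were too few for a list test. Mcpt8, Ccr7, Pecam1, Erg, Fn1 and the megakaryocyte marker Itgb3 were below 1 FPKM in every CD45-negative library. The filter therefore left these genes no call but a rise. No epithelial marker reached the filter. Among 36 ribosomal protein genes 7 were higher (adjusted p = 0.393), and 6 of these, Rpl4 among them (log2 0.78 as deposited and -0.16 with trimmed-mean scaling), changed sign under another scaling. Of 20 stress response genes 11 were higher and 2 lower (adjusted p = 0.474), with 2 of the higher members changing sign under another scaling. The lower ones, Ppp1r15a and Slc7a11, lost their calls without any of the CD45-negative libraries (0.0585 to 0.0981) and after scaling to a common sum (0.119 and 0.204). Slc7a11 also lost it without CD45-positive replicate 1 or 3 (0.0890 and 0.0801), and Ppp1r15a with no filter (0.0566). Of 6 megakaryocyte markers Cd9 and Itgb3 were higher and Gp9 lower (0.777). The Gp9 call was lost without any of the CD45-negative libraries (0.0668 to 0.0875), without CD45-positive replicate 1 or 3 (0.0727 and 0.0793), with no filter (0.0575) and after scaling to a common sum (0.0992). The medians of the ribosomal, stress response, megakaryocyte and endothelial lists were 0.31, 0.85, 0.36 and 0.93 as deposited, and turned to -0.63, -0.07, -0.34 and -0.09 with trimmed-mean scaling. For the ribosomal, stress response, megakaryocyte and interferon-γ lists camera pointed down while the medians were above 0. Without CD45-positive replicate 2, over the same genes, the immediate early, inflammatory and MHC class I lists passed upward (3.90e-04, 2.65e-03 and 3.62e-03), as did the checkpoint, dendritic cell and mast cell lists (0.0204, 0.0262 and 0.0221). The checkpoint list did not pass with the filter applied again (0.658). The mast cell list also passed without any of the CD45-negative libraries (0.0336 to 0.0433). With trimmed-mean scaling the mast cell, immediate early, inflammatory, checkpoint and dendritic cell lists passed upward (2.58e-03, 1.57e-03, 2.35e-03, 6.01e-03 and 0.0442) and the ribosomal list downward (6.37e-04). Without globin genes the inflammatory and mast cell lists passed (0.0488 and 0.03). With the replicate number as a block the immediate early, checkpoint, inflammatory and mast cell lists passed upward (7.08e-03, 0.0468, 8.80e-03 and 0.0106). Adjusted over the list alone, the higher counts were 4, 18, 11, 11, 4, 6, 7, 2, 2, 5, 12 and 2 in the order of this paragraph.

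The genes with the largest rises were Ifitm6 (1.85 ± 0.571 to 428 ± 235 FPKM, log2 7.12, adjusted p = 2.53e-04 by limma), Ltf, Anxa1, Lcn2, Prg2, an eosinophil granule protein, Ngp, S100a9, Retnlg, Camp and Chil3, with log2 changes down to 6.24. Of these rising genes Prg2 moved most with a single library, from 6.70 to 5.61 without CD45-positive replicate 1 and 7.90 without replicate 2. The 10 largest falls were all replication-dependent histone genes, whose transcripts mostly end without a poly(A) tail. H4c6 (chromosome 13, 23551286 to 23551668) fell from 120 ± 106 to 6.05 ± 3.62 FPKM (log2 -3.73 ± 0.82 SE, adjusted p = 7.16e-03), followed by H3c2, H2bc3, H2ac10, H4c14, H4c12, H3c7, H2bc6, H2bc18 and H4f16, with log2 changes from -3.69 to -3.12. Within the CD45-negative group H4c6 was at 105, 232 and 22.7 FPKM, and the log2 changes of these histone genes, tested over the same genes, lay between -2.37 and -3.00 without CD45-negative replicate 2 and between -3.85 and -4.65 without replicate 3, while H4c14 alone moved as far without a CD45-positive library (-2.84 without replicate 2). H4c12 lost its call without CD45-negative replicate 1 or 2 (adjusted p = 0.0910 and 0.0622) or CD45-positive replicate 1 or 3 (0.0519 and 0.0670) or with no filter (0.0603), and H2ac10 and H2bc6 without CD45-negative replicate 1 (0.0574 and 0.0536). Over the same genes H2ac10 also lost it without CD45-positive replicate 3 (0.0528).

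In all, 5400 of 9728 genes were called by limma, 4912 higher and 488 lower in CD45-positive cells. The split of directions depended on the scaling: 91.0% of calls were higher in the deposited values, 81.5% without the globin genes, 97.9% after scaling to a common sum, 50% after trimmed-mean scaling (2361 higher, 2363 lower) and 43.8% after median-ratio scaling. The filter bears on the split too. It left 8102 to 8117 genes without 1 of the CD45-positive libraries, and 9696 to 9704 without 1 of the CD45-negative libraries. Genes that passed through the CD45-positive libraries alone could only be called higher. Without CD45-positive replicate 1 there were 3023 calls (2741 higher, 282 lower), and without replicate 2, which stood apart, 5152 calls (3733 higher, 1419 lower, 72.5% higher). The filter left 8102 and 8105 genes there, and over the same 9728 genes there were 4620 calls (4307 higher, 313 lower) and 6737 calls (5315 higher, 1422 lower). Without CD45-negative replicate 1, 2 or 3 the lower calls were 201, 225 and 269, and without CD45-positive replicate 3 they were 329.

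The second comparison set CD45-positive cells of the tumor against those of the spleen, the same gate in different tissues. Most genes of red cell formation, B cells and granulocytes were far lower in the tumor cells. Globin transcripts remained, with Hba-a1 at 5916 to 40541 FPKM. Genes of macrophages, monocyte-attracting chemokines, arginase and the keratins Krt8 and Krt18 were high. Klf1 fell from 404 ± 183 to 0.218 ± 0.159 FPKM (SD, n = 3 and 4), a log2 change of -8.30 ± 0.28 (SE) with an adjusted p of 4.11e-07 by limma. Arg1 (chromosome 10, 24915207 to 24927470) rose from 0.01 ± 0.017 to 738 ± 40.7 FPKM (log2 9.51 ± 0.13 SE, adjusted p = 2.58e-08). Ccl7, Ccl12 and Ccl2, chemokines that attract monocytes and lie together on chromosome 11 (from 82035577 to 82103399), rose to 3098 ± 999, 2819 ± 318 and 4002 ± 1158 FPKM from 0.047, 0.197 and 2.46 FPKM, and the log2 change of Ccl2 was 10.47 (9.75 without splenic replicate 2).

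Ptprc itself did not differ beyond the spread between libraries, at 153 ± 113 FPKM in spleen and 83.3 ± 16 FPKM in tumor (log2 -0.51, adjusted p = 0.463). Splenic replicates decided that value, which was 0.08 without splenic replicate 1 (adjusted p = 0.904) and -1.29 without splenic replicate 2 (adjusted p = 3.02e-03). Cd274 was at 7.70 ± 7.64 and 17.8 ± 5.05 FPKM (log2 1.59, adjusted p = 0.0769). Its log2 change was 2.33 without splenic replicate 1 (adjusted p = 0.0105) and 0.69 without splenic replicate 2, and it passed in a fit over all 10 libraries (0.0401) and after scaling to a common sum (0.0294).

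All 30 tested genes of erythroid maturation and all 20 of haem synthesis and iron uptake fell, and 16 of 18 erythroid transcription factors fell, with the same counts adjusted over the list alone. The median log2 changes were -7.01, -4.03 and -4.50, against 0.203 for all 11463 tested genes (0.054 with trimmed-mean scaling). The camera adjusted p-values were 3.07e-20, 2.10e-12 and 9.53e-10, and with an estimated correlation the adjusted p was 0.309 for each. Slc4a1, the anion exchanger of red cells (chromosome 11, 102348820 to 102365281), fell from 2165 ± 201 to 1.03 ± 1.49 FPKM (log2 -10.29). Rhag and Dmtn were at log2 -8.32 and -6.98, Slc25a37, a mitochondrial iron importer, at -5.80, and the regulators E2f2 and Sox6 at -4.69 and -5.34. Tfrc fell from 707 ± 223 to 16.6 ± 3.29 FPKM (log2 -5.30, adjusted p = 1.78e-06). Hba-a1, a globin gene, fell by less than the median of the maturation genes, from 202506 ± 73773 to 14745 ± 17198 FPKM (log2 -4.29, adjusted p = 1.14e-03, and -4.97 without tumor replicate 1, which held 40541 FPKM). Hbb-bs was too low in both groups for a test (0.867 and 0.208 FPKM). Kit fell from 2.11 ± 0.592 to 0.195 ± 0.096 FPKM. Klf1, Dmtn and Kit were below 1 FPKM in every tumor library, passed the filter through the splenic libraries alone and could only be called lower. The largest falls after Slc4a1 included the granule genes Ngp and Camp (log2 -10.10 and -9.40), which were at 65.6 and 40.4 FPKM in tumor replicate 1 and at most 0.25 FPKM in the other tumor libraries (log2 -11.55 and -10.71 without that replicate, and -8.79 for Camp without splenic replicate 3). Cd24a, Car2, Hemgn, Klf1, Cldn13, Ctse and Car1 were among them too, at log2 -8.98, -8.81, -8.78, -8.30, -8.70, -8.61 and -8.48 (Car1 at -9.12 without splenic replicate 1 and -7.49 without splenic replicate 2).

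Cell cycle genes fell for 31 of 32 genes (32 adjusted over the list alone), with a median log2 change of -1.93 (camera adjusted p = 5.97e-10, and 0.609 with an estimated correlation). Mki67, a marker of proliferating cells, fell from 397 ± 144 to 26 ± 5.50 FPKM, and Ube2c by 2.71 on the log2 scale. Of 22 granulocyte markers 21 fell, also when adjusted over the list alone (median log2 -5.44, adjusted p = 3.90e-09, and 0.560 with an estimated correlation). Among them was Cxcr2, a neutrophil chemokine receptor (log2 -4.41). The remaining one, Trem1, an activating receptor of myeloid cells, was at 10.9 ± 7.72 and 20.1 ± 1.35 FPKM (log2 1.04, adjusted p = 0.0475). Its call was lost without splenic replicate 1 or 2 (0.102 and 0.0828) or any of the tumor libraries (0.0795 to 0.103). Its adjusted p was 0.0513 to 0.238 with a pseudocount of 0.1, no filter, no globin genes, trimmed-mean or median-ratio scaling, or averaged tumor libraries. It was 0.0554 with the replicate number as a block.

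B cell markers fell for all 14 tested genes (median log2 -4.74, camera adjusted p = 2.68e-06, and 0.609 with an estimated correlation). Cd79a fell from 376 ± 276 to 0.405 ± 0.516 FPKM and Cd79b from 216 ± 161 to 1.49 ± 0.329 FPKM. T and NK cell markers fell for 13 of 17 genes (median log2 -2.24, adjusted p = 4.10e-04, and 0.716 with an estimated correlation), Cd3d by 3.38 and Lck by 3.60. Adjusted over the list alone, 14 B cell and 13 T and NK cell markers fell and Gzmb, named after its value was seen, rose. The spread of these genes within the spleen was wide, and without splenic replicate 2, which was low in both groups of markers, the log2 changes of Cd79a and Cd79b were -8.62 and -6.95 in place of -7.62 and -5.91. Cd79a was at -7.03 without splenic replicate 1 and Cd79b at -5.30 without splenic replicate 3.

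Monocyte and macrophage markers rose for 18 of 24 genes and fell for 2, with the same counts adjusted over the list alone (median log2 3.56, camera adjusted p = 5.31e-03, and 0.716 with an estimated correlation). Trem2, a lipid-sensing receptor of macrophages (chromosome 17, 48346401 to 48352276), rose from 1.63 ± 1.10 to 510 ± 139 FPKM, and the scavenger receptor Msr1 from 5.95 ± 4.41 to 746 ± 52.3 FPKM. Spic, a regulator of splenic red pulp macrophages, fell by 4.05 on the log2 scale from splenic values of 77.9, 2.00 and 22.5 FPKM (by 2.97 without splenic replicate 1 and 5.33 without replicate 2). Ly6c2, a marker of classical monocytes, fell by 1.65 (adjusted p = 0.0377), a call lost without splenic replicate 1 or 3 (0.0755 and 0.135) or tumor replicate 1, 2 or 4 (0.0832, 0.0543 and 0.0570), with no filter (0.0604) or with averaged tumor libraries (0.0510 and 0.0723). Inflammatory cytokines and chemokines rose for 21 of 25 genes, also adjusted over the list alone (median log2 5.08, camera adjusted p = 2.68e-07, and 0.564 with an estimated correlation). Besides the chemokines on chromosome 11, which include Ccl8 (0.110 ± 0.191 to 496 ± 194 FPKM), the risers held Spp1, an extracellular matrix glycoprotein (log2 9.32), and Cxcl1 (log2 9.07). Pf4, Pmp22 and Crabp1 completed the largest rises, Pf4 from 1.15 to 667 ± 128 FPKM and Pmp22 from 0.047 ± 0.025 to 294 ± 19.9 FPKM. Crabp1 was listed at 0 in all splenic CD45-positive libraries and at 209 to 294 FPKM in the tumor.

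Glycolysis and hypoxia genes rose for 26 of 30 genes and fell for 2, also adjusted over the list alone (median log2 3.01, camera adjusted p = 2.68e-07, and 0.309 with an estimated correlation). Tpi1 rose from 85.0 ± 16.8 to 1035 ± 41.2 FPKM and the hypoxia-induced Car9 from 0.377 ± 0.219 to 28.2 ± 3.89 FPKM. Hk1 and Slc2a3, a hexokinase and a glucose transporter, fell (log2 -1.93 and -2.76). Immunosuppressive enzymes and cytokines rose for 12 of 18 genes, with Artn alone falling (log2 -0.66), also adjusted over the list alone (adjusted p = 7.33e-03, and 0.695 with an estimated correlation). The Artn call was lost after scaling to a common sum (0.105) and with tumor replicates 2 to 4 averaged (0.0717). Next to Arg1, Nos2, the inducible nitric oxide synthase, rose from 0.027 ± 0.006 to 6.20 ± 0.544 FPKM. Of 18 epithelial markers, which the sorted population need not hold, only 3 reached the filter. All 3 rose, also adjusted over the list alone (camera adjusted p = 8.92e-03, and 0.560 with an estimated correlation). Krt8 and Krt18, the paired keratins of simple epithelia (chromosome 15, from 101996711 to 102032026), reached 219 ± 13.7 and 117 ± 31.8 FPKM from 0.023 and 0.133 FPKM. Both passed the filter through the tumor libraries alone, so the filter left them no call but a rise. The same holds for Arg1, Nos2, Ccl7, Ccl12, Ccl8, Pmp22, Crabp1 and Car9 in this comparison. Fibroblast and stroma markers rose for 10 of 13 genes, also adjusted over the list alone (adjusted p = 1.49e-04, and 0.309 with an estimated correlation), with Col3a1 at 99.0 ± 19.1 and Sparc at 88.6 ± 8.69 FPKM. With tumor replicates 2 to 4 averaged and counted once, the filter left 4 of the 13 stroma genes, which did not pass (adjusted p = 0.408). Over the same 13 genes the list passed (3.47e-05). The genes that the filter removed had passed it before through the tumor libraries, which favors a rise, so this fit is no separate support.

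Antigen presentation genes were called in different directions in class I and class II, though only the class I list passed. Of 17 MHC class I genes 15 rose (camera adjusted p = 8.01e-03, and 0.716 with an estimated correlation), H2-D1 from 235 ± 124 to 1129 ± 131 FPKM. Of 13 class II genes 8 fell and 3 rose (adjusted p = 0.151). H2-Ob and the regulator Ciita fell by 4.58 and 3.37 (5.61 and 4.26 without splenic replicate 2, and 2.66 for Ciita without replicate 1), and the lysosomal proteases Lgmn and Ctss rose by 5.53 and 4.20 on the log2 scale (6.45 and 5.0 without splenic replicate 1, 4.50 and 3.15 without splenic replicate 2). The class II list passed downward without splenic replicate 2 (0.0235). Type I interferon genes rose for 15 of 26 genes and fell for 2 (adjusted p = 0.0185, 0.764 with an estimated correlation, and 0.107 without splenic replicate 2 or 0.0671 over the same genes). Ifit2 rose by 3.42, and Rsad2 fell by 1.59 (adjusted p = 0.0322), a call lost without splenic replicate 1 or 3 (0.104 and 0.119) or any of the tumor libraries (0.0525 to 0.0901), with no filter (0.0525) or with averaged tumor libraries (0.0536 and 0.0896), while its log2 change was -2.30 without splenic replicate 2. Irf9, the other falling member (log2 -0.57, adjusted p = 0.0385), lost its call without splenic replicate 1 or 3 (0.117 and 0.102) or any of the tumor libraries (0.0613 to 0.0891). It also lost it with averaged tumor libraries (0.0653 and 0.143), with the replicate number as a block (0.160) or after scaling to a common sum (log2 -0.31, adjusted p = 0.334). Immediate early and dissociation genes rose for 19 of 26 genes and fell for Btg2 (adjusted p = 0.0142, and 0.716 with an estimated correlation), with Nfkbia and Ier3 rising by 3.93 and 4.53 (Nfkbia by 3.32 without splenic replicate 2). Ribosomal protein genes rose for 20 of 36 genes, 1 of which changed sign under another scaling (adjusted p = 0.0104, and 0.764 with an estimated correlation), Rpl37 by 1.22. The ribosomal list did not pass without globin genes (0.339), with trimmed-mean scaling (0.0846) or without splenic replicate 1 (0.0979). Adjusted over the list alone, 15, 3, 15, 19 and 20 genes rose in these lists, in the order given.

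The remaining lists did not pass camera. Members went both ways among 24 checkpoint genes (13 higher, 4 lower, adjusted p = 0.450), with Btla and Tnfrsf14, which bind each other, lower by 4.35 and 3.39 (Btla by 5.16 without splenic replicate 2) and Cd276 higher by 1.31 on the log2 scale. Among 15 early progenitor genes (7 higher, 5 lower, adjusted p = 0.987) Cd34 rose from 1.60 ± 1.68 to 163 ± 8.41 FPKM and Myb fell by 2.81. Of 19 interferon-γ induced genes 11 were higher and 3 lower (adjusted p = 0.189), Cxcl10 rising by 6.05 and Irgm2 falling by 2.18. Of 8 endothelial markers 5 were higher and 2 lower (0.294), with Kdr at 3.32 ± 0.594 FPKM and Pecam1 lower by 2.30, a call lost without splenic replicate 3 (0.0600) or with tumor replicates 2 to 4 averaged (0.0740), with log2 changes of -1.61 and -3.19 without splenic replicate 1 or 2. Mast cell and basophil markers (1 higher, 4 lower of 6, adjusted p = 0.113), stress response genes (11 higher, 1 lower of 21, 0.135), oxidative phosphorylation genes (11 higher, 1 lower of 30, 0.259), dendritic cell markers (4 higher, 3 lower of 9, 0.779) and megakaryocyte markers (4 higher, 3 lower of 7, 0.779) completed the set. Without splenic replicate 2, over the same genes, the oxidative phosphorylation list passed upward and the mast cell list downward (0.0129 and 0.0423). Megakaryocyte markers without any of the splenic libraries (0.0153 to 0.0473), early progenitor genes without splenic replicate 3 (0.0153) and mast cell markers without tumor replicate 1, 2 or 3 (0.0206 to 0.0278) passed only with the filter applied again to the libraries left, and not over the same genes (0.559 to 0.966, 0.589 and 0.1 to 0.118). The same held with tumor replicates 2 to 4 averaged for mast cell markers (0.0227, and 0.106 over the same genes) and stress response genes (0.0471 and 0.156), and mast cell markers also passed with replicates 2 and 3 averaged (0.0210). Adjusted over the list alone these counts were the same, except that 10 oxidative phosphorylation genes were higher and none lower.

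In all, 7313 of 11463 genes were called by limma, 4327 higher and 2986 lower in the tumor. Of these calls 59.2% were higher in the deposited values, 40.6% with the globin genes left out (2946 higher, 4310 lower) and 70.5% after scaling to a common sum. With tumor replicates 2 to 4, which were close to each other, averaged and counted once, 3643 of 10527 genes were called (1912 higher, 1731 lower), and 4769 (2904 higher, 1865 lower) over the same 11463 genes.

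**Figure D2:**
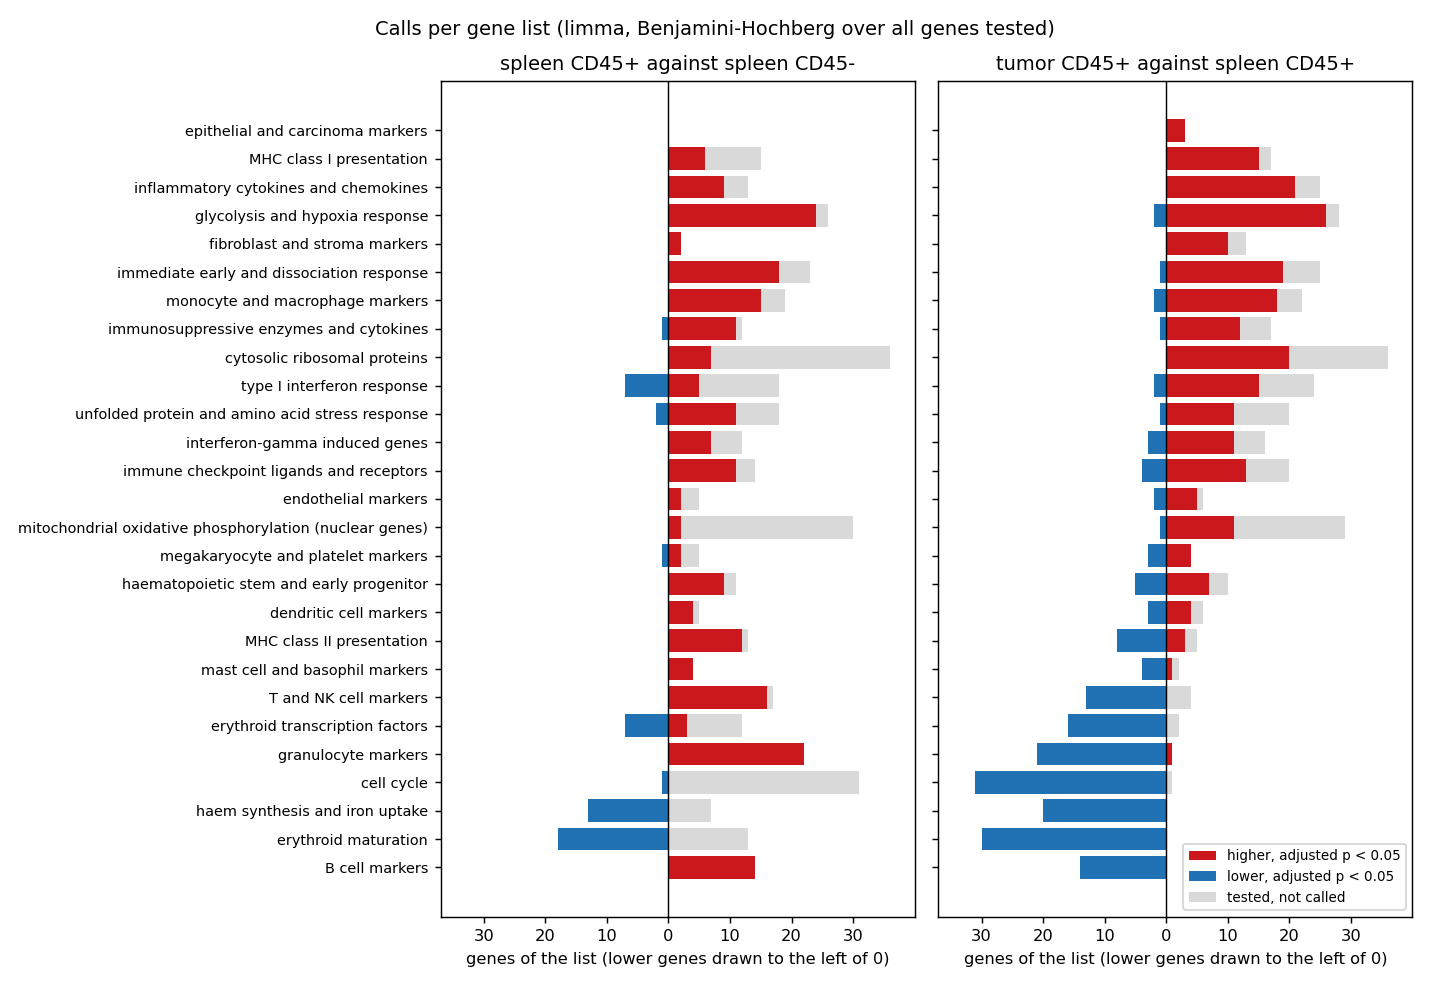
Number of genes of each list called higher (red, to the right of 0), called lower (blue, to the left of 0) or tested and not called (grey) by limma at a Benjamini-Hochberg adjusted p below 0.05, for splenic CD45-positive against CD45-negative libraries (left) and for tumor against splenic CD45-positive libraries (right). All 30 tested genes of erythroid maturation are lower in the right panel against 18 of 31 in the left, and called higher members of the ribosomal (6 of 7), oxidative phosphorylation (2 of 2), stress response (2 of 11) and checkpoint (1 of 11) lists in the left panel change sign under another scaling.

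Both comparisons use the splenic CD45-positive libraries, with opposite sign, so their chance values are linked. Of 9650 genes tested in both, 2018 were higher in splenic CD45-positive than in CD45-negative cells and higher again in the tumor, against 1463 for independent lists. There were 365 lower in both (147 for independent lists), 943 were higher in the spleen comparison and lower in the tumor comparison (1518), and 29 were lower and then higher (142). Simulated unchanged groups against the same splenic CD45-positive libraries shared 0 to 0.65 such calls on average over 20 simulations. The log2 changes correlated at 0.276 across genes, which are not independent replicates, against -0.908 in the simulations, and their covariance was 0.498 against -0.118. In the simulations the shared libraries alone gave a negative relation (correlation -0.915 to -0.901). This argues against them as the source of the excess of calls in the same direction. With 3 shared libraries no split left at least 2 in each part, so the size of their effect was not measured. The overlap was counted on the deposited values alone. Globins held 62.9%, 41.3% and 3.99% of FPKM in splenic CD45-negative, splenic CD45-positive and tumor libraries, which leaves more of the total to other genes at each step. With trimmed-mean scaling the higher calls of the first comparison were 2361 in place of 4912. Whether the excess remains under another scaling was not tested.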

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

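The tests of explanations in this part were chosen after the result was seen, and the counts over other splits of the libraries were fixed before the data were examined. Of 79 values tested in the 4 tumor libraries, 34 had a library whose gap to its nearest neighbour, as a share of the whole range, exceeded Dixon's 95% critical value, which chance gives in about 1 in 20 values. These values are not independent, since tumor replicate 1 was the highest library in 15 of them and the lowest in 16. Groups of 3 libraries were not tested in this way.

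Tumor replicate 1 was highest in red cell and granule transcripts. The gap as a share of the range was 0.992 for the globin share of FPKM (10.4% against 1.80% to 1.87%), 0.989 for Hba-a1 (40541 against 5916 to 6292 FPKM) and 0.934 for Slc4a1 (3.25 against 0.20 to 0.40 FPKM). It was 0.998 for Ngp (65.6 against 0.12 to 0.25 FPKM), 0.997 for Camp, 0.983 for Cd24a, 0.906 for Car2, 0.889 for Cldn13, 0.86 for Ctse and 0.862 for Car1. The same library was also highest in Trem2 (0.941; 717 against 430 to 446 FPKM), Pf4 (0.938), Krt18 (0.863), Crabp1 (0.845) and the sum of FPKM (0.941; 967487 against 801072 to 810896).

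The library was lowest in Ptprc (0.927; 59.4 against 90.1 to 92.5 FPKM), Tfrc (0.976), Cd274 (0.851), Ly6c2 (0.857), Cd3d (0.855), Lck (0.842), Pecam1 (0.833), Col3a1 (0.95) and Ccl8 (0.847; 207 against 554 to 616 FPKM). It was also lowest in the interferon-induced genes Ifit2 (0.848), Rsad2 (0.953) and Irgm2 (0.911), in Nfkbia (0.968) and Btg2 (0.873), in the number of genes at 1 FPKM or more (0.986; 10728 against 10942 to 10945) and in the share of transcript models without a gene symbol (0.833). Single values of other tumor libraries stood apart for Myb (0.9, replicate 2 highest), Cd276 (0.926, replicate 3 highest) and the implied depth (1.0, replicate 4 lowest at 18600000 fragments). Models without a gene symbol, which entered no test, held 0.957% of FPKM in tumor libraries on average, against 0.442% in splenic CD45-negative and 0.703% in splenic CD45-positive libraries.

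The tumor libraries kept globin transcripts at 12.2%, 1.82%, 1.77% and 1.79% of the splenic CD45-negative level, while 27 other genes of erythroid maturation kept a median of 0.184%, 0.0669%, 0.0721% and 0.0812%. Erythroid cells of the splenic type, or reads from splenic libraries, would bring both in 1 proportion, but globin exceeded the median of the others by at least 22.1 times in each tumor library, which argues against them as the whole source. RNA carried over from mature red cells, which hold globin and little else, may be present and cannot be told apart from other sources. Alas2 and Bpgm, which last to the end of maturation, were 5.37 and 4.21 times higher in replicate 1 than in the mean of the others. That is near the 6.6 of Hba-a1, but Slc4a1 was 11.5 times higher. The CD45-positive gate did not keep erythroid RNA out in the spleen, where globins held 29.3% to 52.2% of FPKM. A difference between the tumors was not tested.

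In every other split of the libraries limma called 0 genes, in both comparisons. In the splenic comparison the real split gave 5400 calls, was the 1 of 10 splits with as many, and the splits are too few for a share below 0.05, while the others had up to 278 genes at an unadjusted p below 0.05. In the tumor comparison the real split gave 7313 calls and was the 1 of 35 with as many. That share is below 0.05 only if the 4 tumor libraries are independent, which the labels do not state. Mixing the groups widens the spread within both parts, so few calls could come from the other splits, and chance is not excluded. With tumor replicates 2 to 4 counted once 10 splits remain, too few for a share below 0.05. Of the 35 splits, those other than the real one had up to 3773 genes at an unadjusted p below 0.05.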

How the results depend on the processing

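Scaling to a common sum, trimmed-mean scaling, median-ratio scaling, the averaging of tumor libraries and the fits over the same genes were chosen after the data were seen, and the other settings before. Of the genes fitted, 49 of 68 in the CD45 comparison and 65 of 73 in the tumor comparison stayed on their side of the threshold with their sign in the settings in which they were fitted. Of these genes 52 and 42 were fitted in every setting, and 35 and 36 of them stayed so. For genes 2991 results were the same, 178 lost a call, 6 gained one and 10 reversed. For lists 906 were the same, 49 lost a call, 51 gained one and 3 reversed. Counts were taken as the same if they stayed within 1.5 times, and 176 were the same and 35 moved. These 176 include 21 results of Ptprc in the CD45 comparison, judged by sign and call, which are not among the 2991. The planned count tests (DESeq2, limma voom, size factors and TMM on counts) were not run, since the files hold FPKM. The implied depth makes values below 1 FPKM coarse, and the direction of small changes in the CD45 comparison rests on the scaling.

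In the CD45 comparison a filter of 5 FPKM, which tests fewer genes, gave 3121 calls, 2683 of them higher, and a minimum log2 change of 1 left 204 lower calls. Without globin genes 878 genes were lower, after scaling to a common sum 121, after trimmed-mean scaling 2361 higher and 2363 lower, and after median-ratio scaling 2269 and 2911, since these scalings move the median of all genes. Leaving out 1 library at a time gave 3023 to 5152 calls, 2741 to 3910 higher and 201 to 1419 lower, with the fewest calls without CD45-positive replicate 1 and the most lower calls without replicate 2. Over the same genes these fits gave 3964 to 6737 calls, with 206, 229 and 276 lower without a CD45-negative library and 313 and 1422 without CD45-positive replicate 1 or 2. In the tumor comparison tumor replicates 2 to 4 averaged, which leaves fewer libraries, gave 3643 calls (1912 higher, 1731 lower), and 4769 (1865 lower) over the same genes, a minimum log2 change of 1 gave 4816 (1871 lower), and a common sum left 1987 lower. A log2 minimum of 1 made the overlaps 1093 (higher in both), 10 (lower, then higher), 414 (higher, then lower) and 114 (lower in both).

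With an estimated correlation 1 list passed in the CD45 comparison and 0 in the tumor comparison, against 14 and 17 with the preset value and 20 and 16 with trimmed-mean scaling. Fry, which does not compare a list with other genes, gave the upward direction for megakaryocyte markers (adjusted p = 2.52e-02), oxidative phosphorylation (8.21e-01), the stress response (1.97e-02), ribosomal proteins (0.110) and interferon-γ induced genes (0.167) in the CD45 comparison, where camera had pointed down. By fry 17 lists passed there, 15 upward and 2 downward. Erythroid transcription factors (0.172), cell cycle (0.463) and type I interferon genes (0.608), which passed camera, did not pass fry. With trimmed-mean and median-ratio scaling Tfrc was at log2 -0.55 and -0.55, Rpl4 at -0.16 and -0.15, Cox5a at -0.09 and -0.09 and Ndufb5 at -0.13 and -0.12, since the scaling shifts all genes down. Ptprc in the tumor comparison ranged from -1.29 without splenic replicate 2 to 0.08 without splenic replicate 1, and the cause was not tested. Deviations of same-numbered libraries from their group means correlated at 0.105, 0.07 and -0.012 between the splenic groups. Between splenic CD45-positive and tumor libraries they correlated at -0.191, -0.092 and -0.083. Between splenic CD45-negative and tumor libraries the values were 0.293, 0.116 and -0.028, and differently numbered pairs reached 0.296. The numbers showed no consistent pairing, but a shared origin of single libraries is not excluded. With the replicate number as a block 4851 and 5684 genes were called and 18 and 17 lists passed.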

Other observations

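All tests and gene choices in this part were made after the values were seen. Outside globins, the transcripts of highest mean differed between the groups. In splenic CD45-negative cells Gpx1, an antioxidant enzyme abundant in red cells, led with 6380 ± 782 FPKM (SD, n = 3), against 3105 in splenic CD45-positive and 1085 in tumor CD45-positive cells, followed among erythroid genes by Slc4a1, Cd24a, Car2 and Alas2 at 4755, 4583, 4107 and 3221 FPKM. In splenic CD45-positive cells S100a8, the partner of S100a9, led with 20920 ± 13421 FPKM (SD, n = 3), against 252 in CD45-negative and 281 in tumor cells. In tumor CD45-positive cells Lyz2 and the actin-binding peptide gene Tmsb4x led with 17721 ± 7825 and 15570 ± 819 FPKM (SD, n = 4). The light and heavy ferritin genes Ftl1 and Fth1 stood at 6810 and 6727 FPKM there. B2m, the light chain of MHC class I, was at 5740 FPKM against 1178 in splenic CD45-positive cells, and Lgals1, a galectin, at 5503 against 79.6 FPKM.

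Splenic CD45-negative replicate 1 held low amounts of transcripts that were abundant in the tumor libraries. Arg1 was at 1.26 FPKM in it, against 0.03 and 0 in the other two libraries of its group and 738 in the tumor. Col3a1 was at 0.68 FPKM against 0 and 0.02, and Pmp22 at 0.39 against 0 and 0.02.

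Of 57 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 54 fell in splenic CD45-positive cells, against 488 of all 9728 tested genes. All CD45-negative libraries lay above all CD45-positive ones for 53, an order that chance gives in 5% for a single gene. The group was looked at because the largest falls of this comparison belonged to it. Its genes also varied together between libraries, so these counts are neither separate observations nor a test against chance. Their median was 47.4, 104 and 16.2 FPKM in the CD45-negative libraries and 5.55, 5.51 and 6.11 in the CD45-positive libraries. More dividing cells in some CD45-negative libraries are argued against, since the cell cycle list differed by a median log2 ratio of 0.12 (SD 0.3, 32 genes) between replicates 2 and 3 while the histone genes differed by 2.56 (SD 0.9, 56 genes). A candidate explanation is that the capture of RNA without a poly(A) tail differed between libraries, since 6 polyadenylated histone variants differed by -0.09 (SD 0.19). That test concerns the spread within the CD45-negative group, and the difference between the groups stays open, with a biological one untested.

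B cell markers in splenic CD45-positive replicate 2 were at a median of 0.113 of replicate 1. The log2 ratios had an SD of 0.41, at percentile 0.33 of random lists matched on mean, which is consistent with cells of 1 type taken in at a lower share. The depths of these replicates had a ratio of 1.05, but FPKM values are already divided by depth, so that ratio decides nothing. A single change in the share of all leukocytes is argued against by a difference of 3.33 on the log2 scale between granulocyte and B cell markers. Against replicate 3, where granulocyte markers were low too (0.38), that difference was 1.51. A CD45 gate would not remove leukocytes, and the B cell receptor component Cd79a was at 593 and 64.9 FPKM in replicates 1 and 2. Other expression within the sorted cells was not tested.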
